A study of Mus musculus with 6 samples.

How the data were processed

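Total RNA of mouse bone marrow cells was labelled with Cy3 and hybridised to 1-colour Agilent whole-genome arrays, 1 array per sample, per the labels' protocols. The deposited scanner files hold spot intensity values from Agilent Feature Extraction 10.7.3.1, per the file headers, on a linear scale with the scanner software's background subtraction in the processed signal. The deposited value table holds log2 values, and how the authors scaled them is not given in the sources used here. Set against the scanner values, the table matched log2 processed signals scaled to the 75th percentile and centred on each probe's median over the 6 arrays, with a lowest slope of 0.9988 and a median absolute difference of at most 0.013. Its direction is therefore settled. The column medians were -0.103 for the untreated array, -0.0569 and -0.0975 for the PBS arrays, and 0.117, 0.0111 and 0.0867 for the rHuEPO arrays.

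From the scanner files, log2 of the processed signal minus the array's 75th percentile over gene spots was computed. The 1639 control spots and spots flagged as outliers were left out, spots of 1 probe were averaged, and 17 probes without a usable value on some array were left out. No spot was saturated. A probe was tested when it was well above background on at least 3 of the 6 arrays, which kept 19590 of 41174 probes. A gene was represented by its brightest tested probe. Of 3798 genes with more than 1 tested probe, 1143 had probes whose changes differed in sign. The files carry no gene name column, so names were taken by matching accessions without versions to a RefSeq table of assembly GRCm38.p6. Of the probes 26690 (64.8%) matched and 14484 did not, and the latter kept the file's identifier. The array design's coordinates belong to another build, so none are given. The 14853 genes tested comprise 11211 with a symbol and 3642 without.

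Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The main fit set the 3 rHuEPO arrays against the 3 control arrays, as the study's design does. A fit with 3 groups gave rHuEPO against PBS and untreated against PBS. Where a probe was not well above background on any array of an arm, the difference is a bound. It sets the bright arm's mean against the mean, per dim array, of the higher of the probe's own value and the lowest value among probes well above background there. Limma tested the readings themselves, dim ones included, so a p-value given beside a bound does not test the bound. Gene lists were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. Of 688 list members 605 were tested, 53 were too dim and 30 had no matched probe. Slide and scan fell together, and slide was fitted as a block. Median change over all genes was -0.015, and it moved to 0.059 with median scaling and 0.07 with normexp and the 75th percentile. Correlations between arrays ranged from 0.9636 to 0.9914, so no pair was treated as 1 sample.

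The genes named were fixed by rule before the data were examined. They are up to 12 genes per direction with the largest change among those that passed with the arms fully separated, leaving out unnamed, clone, predicted and pseudogene entries, or the 6 with the smallest p where none passed. A fixed panel is given whatever its values, with the members of each list that have the smallest p (4 per list, of which the text gives the first 2 for most lists that did not pass), and 5 per direction for the other comparisons. Some genes that this rule picks are not reported here.

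The gene test was tested on simulated data for rHuEPO against control, made from the real means and residual spread of 14853 genes with 200 changed. It recovered 44% of the genes changed 2-fold, 78% at 4-fold, 94% at 8-fold and 100% at 16-fold, with 12 false calls. The noise was drawn independently for each gene, without a slide effect. The adjustment is stricter where fewer genes pass, as in the real comparison with its 10 calls. These shares may therefore overstate what could be detected there. Simulated lists of 20 independent genes shifted by 0.5 were found in 3 of 3 cases by camera with either correlation, with 0 false calls among the other lists.

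Alternatives tried were quantile and median scaling, normexp background correction with an offset of 50, no filter or a filter on all 6 arrays, the deposited value table, PBS as the only control, an intensity trend with a robust prior, the mean of all probes, slide or replicate number as a block, array weights and leaving out each array. Normexp was planned on mean signals, a column the files used here do not carry, and was run on median signals instead. That alternative, slide 2 alone, and the lists without Erfe and Cish were added after seeing the data.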

Results

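Bone marrow cells from the femurs of ISAM mice were profiled on 6 one-colour Agilent arrays. ISAM mice lack the endogenous Epo gene and carry an Epo transgene that leaves the adult animal short of erythropoietin and anemic. All animals were male and 10 weeks old. In 3 samples recombinant human erythropoietin (rHuEPO) had been injected into the peritoneal cavity at 3000 U/kg, 6 h before collection. The control arm was made of 2 samples taken 6 h after an injection of phosphate-buffered saline (PBS) and 1 untreated sample. The labels number the samples as replicates without naming separate animals, so p-values measure only the spread between these samples. The number of arrays limits the precision of every value. Each array's 75th percentile signal lay between 220.7 and 264. Between 46.2% and 46.6% of the gene spots were well above background on the rHuEPO arrays and between 48.6% and 50.5% on the control arrays. The median signal of the negative control spots was 4.73 to 5.51 on the rHuEPO arrays and 3.74 to 4.03 on the control arrays, so the arms also differed at the dim end of the scale. Slide 1 held the untreated sample and rHuEPO replicate 1, and slide 2 held the other 4 arrays. Changes below are log2 differences, rHuEPO minus control, with the standard error (SE) from limma.

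The Epo gene was looked at first, although without a wild-type sample its reading could not test the genotype. Neither of its probes was well above background on any of the 6 arrays, so no level could be compared. The receptor gene Epor was measured on every array and its change was 0.31 ± 0.24 (SE, 3 against 3 arrays; limma adjusted p = 1.00).

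The main comparison asked which marrow transcripts had responded to rHuEPO by 6 h. Erfe, which encodes the erythroblast hormone erythroferrone that lowers hepcidin, rose the most. It was not well above background on any control array and was so on all 3 rHuEPO arrays, at least 24.1-fold higher. Cish, a feedback inhibitor of cytokine receptor signalling through STAT5, rose by 4.16 ± 0.30 (SE, 3 against 3 arrays), a 17.9-fold difference. Plek2, a pleckstrin family gene of erythroid cells, rose by 2.65 ± 0.23, and Noct, the deadenylase-like gene nocturnin, by 1.88 ± 0.19. In all, limma with Benjamini-Hochberg adjustment called 10 of 14853 genes higher and 0 lower. At an unadjusted p under 0.05 it listed 736 genes, 363 higher and 373 lower, where a share of 0.05 of all genes is 742.7. That share is not the chance count of this fit, which leaves slide differences in the residual spread. Other splits of the 6 arrays into 3 and 3 that kept the slide 1 arrays apart, and that mix the arms, listed 125 to 362. With slide as a block limma listed 1680 at that level, 835 higher and 845 lower, and no other split was fitted with that block.

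Erfe's adjusted p by limma was 3.17e-05, and it was at least 26.9-fold higher within slide 1 and at least 22.8-fold within slide 2. The adjusted p of Cish was 0.0127 by limma, with 4.53 in slide 1 and 3.97 in slide 2. A further 3 genes had no control array well above background, and their changes are bounds. As for Erfe, their p-values come from the readings themselves, dim ones included, and do not test the bounds. Urah, the enzyme 5-hydroxyisourate hydrolase, was at least 5.75-fold higher (limma adjusted p = 0.0332). Trim15, of the tripartite motif family, was at least 2.51-fold higher (limma adjusted p = 0.0127). Rgs16, a regulator of G protein signalling, was at least 2.21-fold higher (limma adjusted p = 0.0266). Arhgdig rose by 2.94 ± 0.26 and was well above background on 2 of the 3 control arrays (limma adjusted p = 0.0210). Grtp1, a TBC domain gene, rose by 1.90 ± 0.19 (limma adjusted p = 0.0305). The adjusted p was 0.0210 for Plek2 and 0.0305 for Noct by limma. The tenth transcript was a cDNA clone with no symbol in the reference table. For all 9 named genes every rHuEPO array lay above every control array, which was a condition for naming them.

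**Figure D1:**
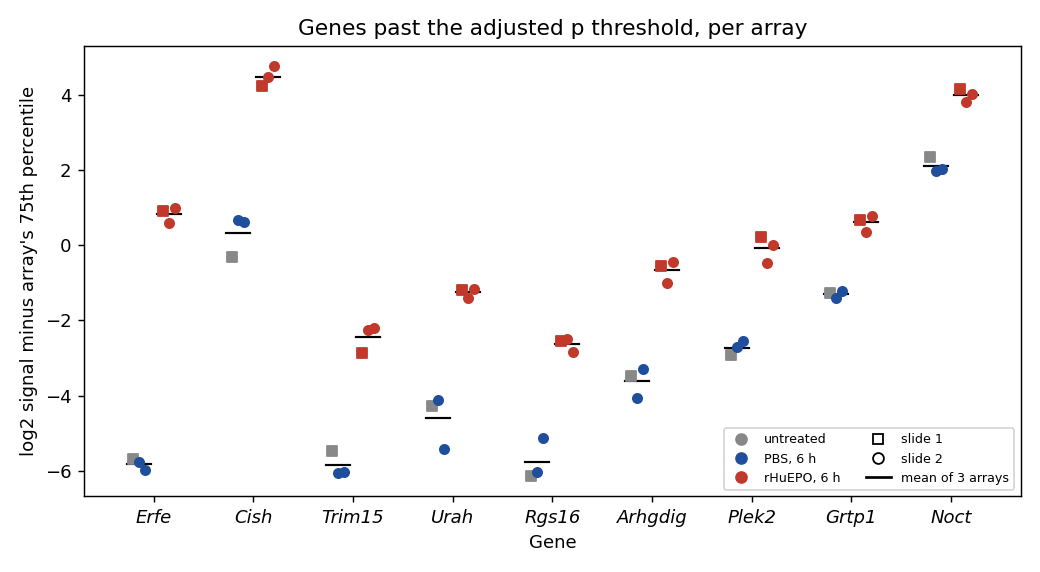
Log2 signal minus the array's 75th percentile (vertical axis) for the 9 named genes past the threshold (horizontal axis), with 1 point per array coloured by group, squares for slide 1, circles for slide 2 and bars for the mean of 3 arrays. The rHuEPO arrays lie above all control arrays for every gene, as the naming rule required, with mean differences of 1.88 for Noct and 4.16 for Cish. The control points of Erfe, Trim15, Urah and Rgs16 are not well above background.

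With slide as a block limma called 11 genes, all higher, and 8 of them were shared with the fit without the block. The differences themselves do not move under this block, because both slides hold the arms in equal proportion. The blocked adjusted p by limma was 0.0001696 for Erfe, 0.00244 for Cish and 0.0301 for Noct. It was 0.0395 for Trim15, Arhgdig, Plek2 and Grtp1 and 0.0495 for Rgs16. The call of Urah ended under the block (limma adjusted p = 0.0643), as did that of the clone. Within slides 1 and 2 Trim15 was at least 1.96-fold and 2.84-fold higher, Urah at least 6.33-fold and 5.48-fold, and Rgs16 at least 2.46-fold and 2.10-fold. The differences were 2.92 and 2.96 for Arhgdig, 3.14 and 2.40 for Plek2, 1.96 and 1.88 for Grtp1, and 1.82 and 1.91 for Noct. Of the 3 genes called only with the block, Apol9b and Igfbp2 are named here after their values were seen, with limma adjusted p of 0.0395 and 0.0495. The other one has no symbol in the table. The number of calls depended on single arrays. It was 3 without the untreated array, 1 without PBS replicate 1, 6 without PBS replicate 2, 3 without rHuEPO replicate 1, 1 without rHuEPO replicate 2 and 1 without rHuEPO replicate 3, and Erfe was called in all 6 of these fits. Cish was called in 3 of the 6, Trim15 in 2, Urah and Rgs16 in 1 each, and Arhgdig, Plek2, Grtp1 and Noct in 0.

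No gene passed the test in the falling direction. The 6 genes with the smallest p there were Ccdc68, Lrrcc1, Adam33, Hyal1, Depp1 and Rec114. Ccdc68 was not well above background on any rHuEPO array and was at least 3.73-fold lower there (limma adjusted p = 0.0584; 0.111 with slide as a block). Lrrcc1, Adam33 and Hyal1 were also not well above background on any rHuEPO array. Adam33 was at least 2.32-fold and Hyal1 at least 1.198-fold lower there, and no bound could be given for Lrrcc1, with limma adjusted p of 0.328, 0.427 and 0.0987. The change was -2.66 ± 0.55 for Depp1 and -1.35 ± 0.29 for Rec114, with limma adjusted p of 0.470 and 0.505. The size for Depp1 is uncertain, since rHuEPO replicate 1 was not well above background. With array weights Ccdc68 and Lrrcc1 passed (limma adjusted p = 0.0202 and 0.0113), the highest over the other settings being 0.711 and 1.00. Over all genes 744 had every rHuEPO array above every control array and 800 had the opposite, together 10.4%. Chance gives 10% for arrays without a slide difference. These arrays differed by slide, so 10% is not an exact reference here.

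Among the panel genes fixed before the data were examined, Erfe and Cish passed the test and no other did. Pim1, a STAT5-induced kinase, had a change of 1.41 ± 0.36 (limma adjusted p = 0.626), and Tfrc, the transferrin receptor, of 0.97 ± 0.19 (limma adjusted p = 0.427). For both, all 3 rHuEPO arrays lay above all controls. The changes of the suppressors of cytokine signalling were 0.96 ± 0.41 for Socs3, 0.39 ± 0.56 for Socs2 and 0.043 ± 0.26 for Socs1. They were 0.011 ± 0.59 for Osm, 0.23 ± 0.23 for the survival gene Bcl2l1, 0.55 ± 0.41 for Myc and -0.13 ± 0.24 for Trib3. Gata1 and Klf1, the erythroid transcription factors, had changes of 0.66 ± 0.34 and 0.56 ± 0.26. Those of the red cell genes Alas2 and Hba-a1 were -0.072 ± 0.28 and -0.015 ± 0.17. The secreted factors Gdf15 and Twsg1 had changes of -0.44 ± 0.70 and 0.010 ± 0.28. No probe was matched to the symbol Hbb-b1, but the beta-globin gene Hbb-bt was measured, with a change of 0.015 ± 0.16. Podxl was too dim to test.

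Gene groups were compared through 30 lists fixed before the data were examined. With camera at a preset inter-gene correlation of 0.01, 11 of the 30 lists lay higher after rHuEPO and 0 lower. With an estimated correlation 0 of the 30 passed, and the smallest adjusted p was 0.364. Among the 11 lists the estimate ran from -0.010 for monocytes and macrophages to 0.57 for the erythrocyte membrane. It was 0.48 for MYC and ribosome biogenesis, where the preset treats the members as nearly independent. For the JAK2-STAT5 targets (0.015) and monocytes and macrophages it was near the preset. Its size thus does not explain the loss of those calls, and the cause was not tested. Passing 0 of the 30 lists is therefore not by itself evidence that correlated members made the calls at the preset. With slide as a block 9 passed at the preset correlation and 0 at the estimated one (smallest adjusted p = 0.526). Fry, which asks whether a list's genes move on balance one way, called 1 list, and its test for change in either direction called 4. Those 4 were the JAK2-STAT5 targets and iron handling (fry either-direction adjusted p = 5.834e-06 for both; 0.0003022 with slide as a block), the glucocorticoid response (0.01167; 0.004894) and the interferon response (0.03315; 0.01737). With slide as a block this test also passed apoptosis regulators (fry adjusted p = 0.004894), ATF4 targets (0.01002), autophagy (0.03598) and heat shock (0.04143). It gives no direction and does not set a list against the other genes. A list is called higher below by camera at the preset correlation, as a shift of these samples.

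The MYC and ribosome biogenesis list had the largest median change over all arrays, while the JAK2-STAT5 targets had a larger mean change (0.81 against 0.56). The median change of the 31 tested members of the MYC list was 0.57, all 31 lay above 0, and for 21 every rHuEPO array exceeded every control array. No member passed the test over all genes or adjusted over the list alone, and 17 passed adjusted over the list alone with slide as a block. The 4 with the smallest p were the nucleolar genes Noc4l (0.92 ± 0.20), Rrp9 (0.86 ± 0.23), Rrp12 (1.00 ± 0.29) and Mybbp1a (0.57 ± 0.17). The list's camera adjusted p was 3.03e-22, against 2.18e-18 with slide as a block and adjusted p = 0.380 with an estimated correlation. Its median was 0.44 within slide 1 and 0.61 within slide 2.

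Interferon response genes had a median change of 0.46 over 28 tested members, with 27 above 0 and 10 separated from all controls. None passed over all genes, and 3 passed adjusted over the list alone (8 with slide as a block). Isg15, a ubiquitin-like interferon-induced protein, had a change of 1.82 ± 0.23 (limma adjusted p = 0.0671; 0.00763 with array weights and up to 0.843 in other settings). The others with the smallest p were Usp18 (1.27 ± 0.23), Irf7 (0.78 ± 0.17) and Ifi35 (0.75 ± 0.21). The camera adjusted p was 6.41e-12, against 1.36e-10 with slide as a block and adjusted p = 0.380 with an estimated correlation. The median was 0.34 in slide 1 and 0.48 in slide 2. The T and NK cell list and the monocyte and macrophage list lay higher beside it. The T and NK cell list had a median of 0.17 over 20 members (camera adjusted p = 0.0143; 0.0220 with slide as a block; adjusted p = 0.746 with an estimated correlation), with Cd8a at 0.39, Gzmb at 0.47, Lat at 0.54 and Skap1 at 0.29. The monocyte and macrophage list had a median of 0.24 over 26 members (camera adjusted p = 0.0151; 0.0199 with slide as a block; adjusted p = 0.380 with an estimated correlation). Its smallest p belonged to Timd4, which was at least 1.09-fold lower, followed by C1qa at 0.52, Siglec1 at 0.75 and Mrc1 at 0.53. Within slides 1 and 2 the medians were 0.093 and 0.17 for T and NK cells and 0.15 and 0.22 for monocytes and macrophages. No member of either list passed over all genes or adjusted over the list alone.

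Of 18 tested JAK2-STAT5 targets 16 lay above 0 and 2, Erfe and Cish, passed over all genes (3 adjusted over the list alone, 4 with slide as a block). Socs3 and Pim1 followed by p. The list's median was 0.12. The camera adjusted p was 6.36e-05, 0.0002333 with slide as a block and adjusted p = 0.364 with an estimated correlation, and fry gave an adjusted p of 0.0200, which was 0.0683 with slide as a block, so that this call ended. Left without Erfe and Cish, an alternative chosen after seeing the data, its camera adjusted p was 0.0748. The erythroferrone and iron handling list had a median of 0.068 over 25 members, with Erfe its 1 member past the test over all genes (2 adjusted over the list alone, also with slide as a block). Tfrc and Tfr2 (0.52 ± 0.33) were among the next by p. Its camera adjusted p was 0.0143, with 0.0681 under the slide block, adjusted p = 0.708 with an estimated correlation, and 0.177 without Erfe and Cish. Its median was -0.020 in slide 1 and 0.068 in slide 2, and that of the JAK2-STAT5 targets was 0.055 and 0.21. The MAPK immediate-early list had a median of 0.19 over 13 members. Egr1 led it (3.03 ± 0.65, limma adjusted p = 0.505) but was well above background on only 2 of the 3 control arrays, so its size is uncertain. Jun was at 0.47, Dusp1 at -0.63 and Ier3 at 0.71. Against PBS alone the differences were 0.59 for Jun, -0.15 for Dusp1 and 0.092 for Ier3. The values of Dusp1 and Ier3 thus rest largely on the lone untreated array, which differed from PBS by 1.44 and -1.86. No member passed over all genes and 1 did adjusted over the list alone (0 with slide as a block). Its camera adjusted p was 0.0329, with 0.059 under the slide block and adjusted p = 0.746 with an estimated correlation, and the slide medians were 0.50 and 0.28.

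Of the 6 erythroid lists, those of the red cell membrane and of heme synthesis lay higher, beside iron handling above. The erythrocyte membrane and late erythroid list had a median of 0.19, with 28 of 33 members above 0. The spectrin gene Sptb (1.24 ± 0.21), the adducin gene Add2 (0.94 ± 0.22), the glycophorin gene Gypc (0.94 ± 0.23) and Rhag (0.86 ± 0.22) had the smallest p. None passed over all genes, and 4 passed adjusted over the list alone, with and without slide as a block. The camera adjusted p was 0.0001002, 0.00123 with slide as a block and adjusted p = 0.746 with an estimated correlation. The heme synthesis list had a median of 0.29, with 11 of 13 members above 0, among them Cpox (0.91 ± 0.40) and Tspo2 (0.42 ± 0.27), and with Slc25a38 at -0.40 ± 0.18. None passed over all genes or over the list alone. The camera adjusted p was 0.00797, 0.0151 with slide as a block and adjusted p = 0.746 with an estimated correlation. Slide medians were 0.32 and 0.19 for the membrane list and 0.34 and 0.26 for heme synthesis. With 1 array left out the median ranged from 0.0587 to 0.419 for the membrane list and from 0.129 to 0.399 for heme synthesis. The membrane score of PBS replicate 2 (0.230) lay above those of rHuEPO replicates 2 (-0.0416) and 3 (0.181). Its heme synthesis score (0.113) lay above those of rHuEPO replicates 1 (0.0388) and 2 (0.00298). The globin list (median 0.0011 over 5 members), the erythroid transcription factors (0.22 over 17) and the progenitor and early erythroid list (0.019 over 16) did not pass, with camera adjusted p of 0.961, 0.121 and 0.926.

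Amino acid stress and ATF4 targets had a median of 0.27, with 19 of 24 above 0. The one-carbon enzymes Shmt2 (0.92 ± 0.23) and Mthfd2 (1.11 ± 0.39), the amino acid carrier Slc7a5 (0.88 ± 0.32) and the asparagine synthetase Asns (0.46 ± 0.18) led by p. None passed over all genes or adjusted over the list alone, and 2 did over the list alone with slide as a block. The camera adjusted p was 0.0002601, 0.0003101 with slide as a block and adjusted p = 0.708 with an estimated correlation. The heat shock list had a median of 0.46, with 12 of 14 above 0, and its leading chaperone genes were Hspa8 (0.49 ± 0.17), Dnaja1 (0.48 ± 0.18), Hspd1 (0.49 ± 0.21) and Hsph1 (0.69 ± 0.31). None passed over all genes or adjusted over the list alone, and 6 did over the list alone with slide as a block. Its camera adjusted p was 0.0002601, 8.61e-05 with slide as a block and adjusted p = 0.719 with an estimated correlation. Slide medians were 0.26 and 0.26 for ATF4 targets and 0.15 and 0.46 for heat shock. Without the untreated array, that is against PBS alone, the medians were 0.147 for ATF4 targets and 0.260 for heat shock, and the untreated minus PBS median of the ATF4 targets was -0.312. The heat shock score of rHuEPO replicate 1 (-0.261) lay below those of both PBS arrays (-0.126 and -0.0148).

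Single arrays ended several of the list calls. Without PBS replicate 1 the camera adjusted p was 0.910 for MAPK, 0.426 for iron handling, 0.427 for heme synthesis, 0.753 for the membrane list and 0.910 for T and NK cells. Without rHuEPO replicate 1 it was 0.483, 0.0781, 0.0964, 0.0804 and 0.483 in the same order and 0.0804 for monocytes and macrophages, and 6 lists passed in all. The monocyte and macrophage call also ended without PBS replicate 2 (0.123) and without rHuEPO replicate 2 (0.0667). The lowest and highest medians over the 6 fits were 0.0747 and 0.354 for MAPK, 0.0170 and 0.126 for iron handling, 0.138 and 0.283 for JAK2-STAT5, 0.277 and 0.617 for interferon, 0.00590 and 0.316 for T and NK cells and 0.130 and 0.248 for monocytes and macrophages.

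**Figure D2:**
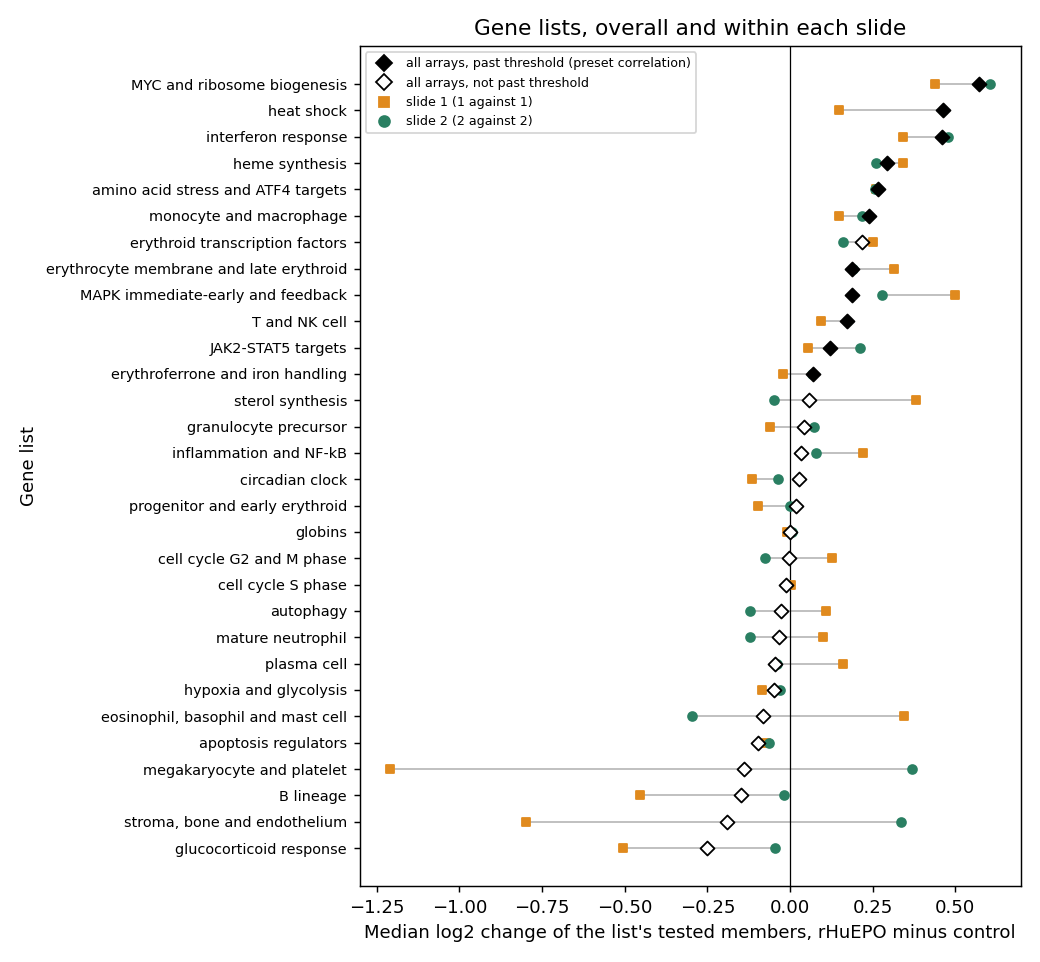
Median log2 change, rHuEPO minus control, of the tested members of each of the 30 gene lists (horizontal axis; 1 row per list), with diamonds for all 6 arrays, filled where camera at the preset correlation passed, squares for slide 1 and circles for slide 2. The MYC and ribosome biogenesis list has the highest median over all arrays, 0.57, with 0.44 in slide 1 and 0.61 in slide 2, and the megakaryocyte list is at -1.21 in slide 1 and 0.37 in slide 2.

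The other lists did not pass camera. Among growth lists, S phase had a median of -0.013 over 29 members (Tk1 at -0.23), G2 and M phase of -0.0029 over 29 (Nusap1 at -0.41, Ccnb1 at 0.36) and apoptosis regulators of -0.097 over 26 (Pmaip1 at 0.98, Trp53inp1 at -0.67). Camera gave adjusted p of 0.931, 0.931 and 0.347. Hypoxia and glycolysis had a median of -0.049 (Hk1 at 0.58, Ankrd37 at -0.79), sterol synthesis of 0.059 (Lss at 0.49, Sqle at 0.38) and autophagy of -0.027 (Gabarapl1 at 0.62, Ulk1 at -0.49), with camera adjusted p of 0.840, 0.177 and 0.840. The glucocorticoid response list had a median of -0.25 (camera adjusted p = 0.177). In it the metallothionein Mt2 was at 1.52 ± 0.26 and Cdkn1c at -0.75 ± 0.20, with Cdkn1c well above background on only 1 of the 3 rHuEPO arrays. Adjusted over the list alone 1 member was higher and 1 lower, or 2 and 2 with slide as a block. The circadian list had a median of 0.027 and a mean of -0.15, opposite in sign, with the test's direction down (Bhlhe40 at 0.35, Per1 at -1.08; camera adjusted p = 0.840). Inflammation and NF-kB genes had a median of 0.034 (Ccl3 at 0.53, Tnf at 0.48; camera adjusted p = 0.461).

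Of the lists for other marrow cell types, mature neutrophils had a median of -0.034 (Camp at -0.36, Padi4 at -0.26), granulocyte precursors of 0.042 (Igsf6 at -0.17, Gfi1 at -0.13) and eosinophils, basophils and mast cells of -0.082 (Gzmb at 0.47, Il5ra at -0.46). Their camera adjusted p was 0.840, 0.977 and 0.840. The B lineage list had a median of -0.15 (Cd74 at 0.37, H2-Aa at 0.64) and varied most within the control arm, with scores of -1.38 on PBS replicate 1, 0.95 on PBS replicate 2 and 0.55 on the untreated array. The megakaryocyte and platelet list had a median of -0.14 (F2r at 1.16, Nrgn at -0.34), with scores of -1.11 on rHuEPO replicate 1 and 0.89 on rHuEPO replicate 2. The stroma, bone and endothelium list had a median of -0.19 (Mmp13 at 2.08, past the test with array weights only, and Runx2 at -0.33), -0.80 in slide 1 and 0.34 in slide 2, and 1 member passed adjusted over the list alone. The plasma cell list had a median of -0.044 and a mean of -0.012 while the test's direction was up (Xbp1 at 0.36, Fkbp11 at 0.62). For each of these 4 lists camera gave an adjusted p of 0.926. For globins (mean -0.011) and progenitors (mean -0.0057) the mean was below 0 while the median and the test's direction were above it.

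Leaving the untreated sample out of the contrast compared rHuEPO with PBS alone, the injection-matched control. Both PBS arrays lay on slide 2 and rHuEPO replicate 1 on slide 1, so this contrast is not balanced for slide. Cish rose by 3.85 ± 0.23 (limma adjusted p = 0.00808). Erfe and Trim15, not well above background on either PBS array, were at least 23.5-fold and 2.45-fold higher (limma adjusted p = 0.0003474 and 0.0216). In all 3 genes were called higher and 0 lower, and all 3 were also called in the main comparison. At an unadjusted p under 0.05 limma listed 591 genes. Among the genes with the smallest p in the falling direction, none of which passed, were Ccdc68 (at least 3.29-fold lower), Cacna1g (-1.72), Lrrcc1 (no bound) and Rec114 (-1.57). Without PBS replicate 1 the number of calls was 1.

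The untreated sample was also set against the 2 PBS samples. Limma called 0 genes, with 804 at an unadjusted p under 0.05, 260 higher and 544 lower, and a smallest adjusted p of 0.465. The lone untreated sample was assumed to vary like the other groups. None of the genes with the smallest p passed. On the higher side they were Heatr3 (3.56 ± 0.40, a size left uncertain by PBS replicate 1, which was not well above background), Aldh1a2 (1.58 ± 0.29), Gdpd2 (1.74 ± 0.33), Asgr2 (1.42 ± 0.27) and Cd59a (1.44 ± 0.28), and on the lower side Golga3 (at least 3.92-fold), Rpl30 (-3.32 ± 0.52), Washc1 (-2.43 ± 0.40), Cd300e (at least 7.48-fold) and Wfdc21 (-2.11 ± 0.35). The untreated sample lay on slide 1 and both PBS samples on slide 2, so slide and injection cannot be told apart in this comparison. For each of these genes rHuEPO replicate 1 minus replicates 2 and 3 was smaller in size, with 0.45 for Heatr3 and -1.01 for Rpl30. For Cd300e it had the opposite sign (0.40). The genes were picked for their difference here, so a smaller one there does not separate slide from injection. Without the filter on dim probes limma called 70 of 32288 genes, 67 of them higher.

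**Figure D3:**
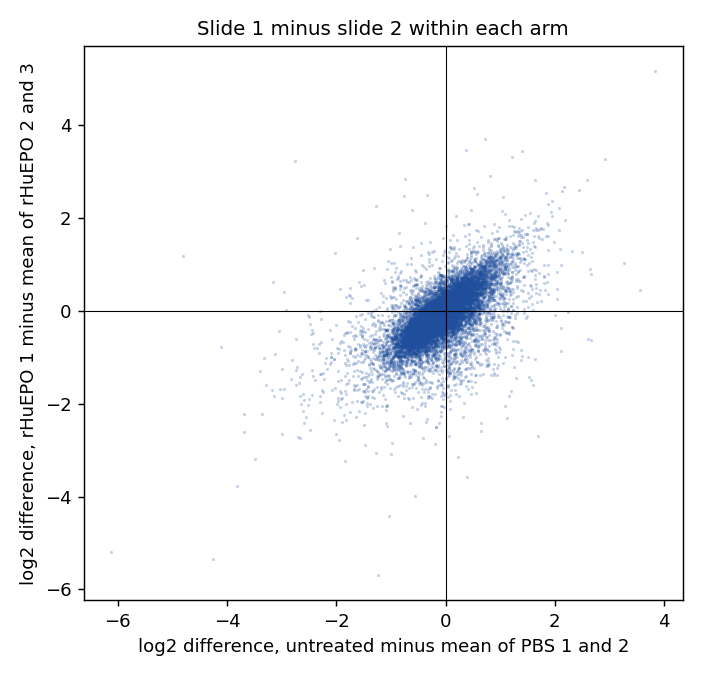
Log2 difference between the untreated array and the mean of PBS replicates 1 and 2 (horizontal axis) against that between rHuEPO replicate 1 and the mean of rHuEPO replicates 2 and 3 (vertical axis), with 1 point for each of 14853 genes. Both axes are slide 1 minus slide 2 within an arm and share no array, and across genes Pearson's r was 0.633.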

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

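The tests of principal components and of cell content below were chosen after the results were seen, and the tests of single arrays and of slide within the MYC and interferon lists were set before, except that their bootstrap intervals were asked to clear the bound only afterwards.

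Podxl, which encodes podocalyxin, was too dim for the test and was noticed because 1 of its 2 probes was well above background on 1 rHuEPO array and on 0 control arrays. The 3 rHuEPO arrays read -3.23, -4.21 and -4.83 and all lay above the 3 control arrays, with a difference of means of 1.85 on the log2 scale and SDs of 0.81 and 0.23. The control readings and those of 2 rHuEPO arrays are below the lowest signal counted as well above background, so this difference measures no fold. The other probe was well above background on 0 of the 6 arrays, with a difference of 0.44. Its rHuEPO readings (-5.18, -5.85 and -5.78) also lay above its control readings (-6.10, -5.98 and -6.04). Podxl was 1 of 54 fixed genes with a matched probe too dim to test. Chance would separate 10% of such genes this way or the other only if the arms were alike at the dim end, and they were not. An Epo probe dim on every array also read higher on the rHuEPO arrays (-5.68, -5.85 and -5.75) than on the controls (-6.10, -5.99 and -6.03). The other Epo probe overlapped, and a dim Twsg1 probe separated lower. Separation alone is therefore not evidence of a rise of Podxl. The difference of 1.85 was larger than the 0.28 of that higher Epo probe, so a rise is neither shown nor excluded, and its size cannot be measured.

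The first principal component, with 47.4% of the variance, separated the slides and not the arms. Untreated minus PBS and rHuEPO replicate 1 minus replicates 2 and 3 share no array, and across genes they correlated with r = 0.633 (95% bootstrap interval 0.615 to 0.652; genes are not independent replicates). Since all 3 rHuEPO samples had been injected, this argues against the PBS injection as the whole cause. Slide, scan and a cohort of mice processed together remain, and cannot be told apart from each other because they coincide in these data.

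The shift of the MYC and ribosome biogenesis list was weighed next. Its lowest median with 1 array left out was 0.40, without PBS replicate 1, so no single array accounts for it. A slide effect common to both arms cancels by design, because both slides hold the arms in equal proportion. The within-slide medians of 0.44 and 0.61 therefore show only that the shift was present on both slides, with 1 array per arm on slide 1. Against more cycling cells, the higher of the S phase and G2 and M phase medians was -0.0029 here, 0.071 with median scaling (list 0.65), -0.014 with quantile scaling (list 0.53) and -0.0091 with normexp and quantile scaling (list 0.41). It reached 0.39 (list 0.78) with normexp and the 75th percentile, and that setting alone leaves the explanation open, under a demand for agreement in every scaling that was made only after its value was seen. More erythroid cells also stay open, since the heme synthesis median of 0.294 lay above the bound of 0.286 and the late erythroid median of 0.189 below it. The globin list, with a median of 0.0011, stood in an earlier form of this test and was replaced after the main results were seen. A response within the cells of the rHuEPO arm is a further hypothesis that bulk RNA does not separate from a change in cell content.

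The interferon list had within-slide medians of 0.34 and 0.48, so its shift was also present on both slides, and a common slide effect cancels here too. Its median was 0.28 without rHuEPO replicate 2 (bootstrap interval 0.020 to 0.487), so a large part may rest on that array. The monocyte and macrophage median of 0.24, without genes shared with the list, leaves more of those cells open. An effect of rHuEPO on interferon genes is therefore only 1 of several hypotheses.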

How the results depend on the processing

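Tests on normexp with median signals, slide 2 alone and the lists without Erfe and Cish were chosen after the data were seen, and normexp on mean signals was not run. Every named called gene kept its direction, but with normexp and the 75th percentile the fitted change of Trim15 was 0.040, of Rgs16 0.030, of Urah 0.54 and of Arhgdig 0.74, none of them past the test. The 10 calls became 3 with normexp and quantile scaling, 1 with normexp and the 75th percentile, 1 without the filter (32288 genes tested), 5 with the filter on all 6 arrays, 3 against PBS arrays alone or in the 3-group model, 3 in slide 2 alone, and 27 with array weights, 3 of them lower (Ccdc68, Lrrcc1 and Cacna1g). Array weights also called Isg15 (adjusted p = 0.00763 by limma) and Mmp13 (0.0477), with highest values over the settings of 0.843 and 1.00. Leaving out 1 array gave 1 to 6. Erfe was called in 13 of the 14 settings that tested it, leave-one-out fits aside, and not with normexp and the 75th percentile (2.08, adjusted p = 0.711 by limma; range over the settings 1.16e-05 to 0.711), and the cause was not tested there or for the list values below. With the replicate block 1 gene was called, Erfe. Replicate numbers did not pair the samples (correlations of deviations -0.0714 and -0.16 for the 2 shared numbers), and that block gave list adjusted p of 0.103 for iron handling, 0.0587 for heme synthesis and 0.0285 for glucocorticoid response. Against PBS alone 3 calls became 1 without the filter and 1 with the filter on all 6 arrays, and 1 to 3 with 1 array left out. Untreated against PBS gave 70 without the filter and 0 to 0 with 1 array left out.

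The 11 list calls became 3 without the filter, 0 with an estimated correlation, 1 with fry, and 6 to 13 with 1 array left out. Adjusted p for lists that changed side or direction follow. Without the filter they were 0.153 for JAK2-STAT5, 0.813 for iron handling, 0.554 for heme synthesis, 0.418 for the erythrocyte membrane, 0.357 for ATF4, 0.169 for heat shock, 0.940 for monocytes, 0.712 for T and NK cells, 0.992 for MAPK (direction turned) and 0.0317 for apoptosis. With an estimated correlation they were 0.364 for JAK2-STAT5, 0.746 for MAPK, heme synthesis, the membrane and T and NK cells, 0.380 for MYC, interferon and monocytes, 0.708 for iron handling and ATF4, and 0.719 for heat shock. With fry they were 0.853 for MAPK, 0.218 for MYC, 0.142 for iron handling, 0.843 for heme synthesis and the membrane, 0.697 for ATF4 and heat shock, 0.333 for interferon and monocytes, and 0.885 for T and NK cells. MAPK gave 0.061 with quantile scaling, 0.0623 with normexp and quantile, 0.101 with normexp and the 75th percentile, 0.221 with the filter on all 6 arrays, 0.059 with the slide block, 0.538 with array weights and 0.0629 in slide 2 alone. Iron handling gave 0.0731 with normexp and quantile, 0.169 with the filter on all 6 arrays, 0.0681 with the slide block, 0.322 with array weights and 0.177 without Erfe and Cish, which took JAK2-STAT5 to 0.0748. With normexp and the 75th percentile T and NK cells gave 0.669, erythroid factors 0.0007027, and S phase 0.00190, G2 and M phase 0.00581 and neutrophils 0.00808, these 3 turned to higher. Array weights gave 0.769 for heme synthesis, 0.883 for the membrane, 0.358 for T and NK cells, 0.0006064 for B lineage and 0.0008541 for megakaryocytes (turned). Slide 2 alone gave 0.0593 for heme synthesis, 0.0003294 for megakaryocytes and 0.0009413 for stroma (both turned), and 0.0484 for eosinophils. Against PBS alone, in either form, erythroid factors gave 0.0315 and stroma 0.0211 (turned).

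With 1 array left out the adjusted p ranged from 0.00134 to 0.910 for MAPK, 0.00334 to 0.426 for iron handling, 0.0001659 to 0.427 for heme synthesis, 1.53e-08 to 0.753 for the membrane, 0.0192 to 0.767 for erythroid factors, 0.00113 to 0.850 for sterol synthesis, 0.00671 to 0.738 for glucocorticoid response, 0.00365 to 0.123 for monocytes, 3.02e-14 to 0.924 for B lineage (0.0282 and turned without PBS replicate 2), 2.40e-06 to 0.910 for T and NK cells, 9.97e-06 to 0.952 for megakaryocytes (0.0003654 and turned without rHuEPO replicate 1) and 0.00748 to 0.940 for stroma (0.0211 and turned without the untreated array). The MYC, interferon, heat shock, ATF4 and JAK2-STAT5 calls held in all 6 of these fits, with highest values of 3.42e-12, 1.74e-06, 0.00949, 0.00480 and 0.0229. A further 70 list and 94 gene values turned sign without being called on either side. Dim probes limit the folds, since 53 list members were too dim to test.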

Other observations

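The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For single genes the real split gave 10 calls and the highest of the others 3, so 1 of the 10 splits gave as many as the real one, itself. For gene lists at the preset correlation the real split gave 11 calls and the highest of the others 17. In all, 5 of the 10 splits gave at least as many lists, among them 1 that put both slide 1 arrays on the same side. The number of lists past the threshold was thus no larger than that of several groupings that mix the arms. The unadjusted camera p of the MYC list was 1.009e-23 in the real split, against 4.132e-12 and 2.321e-09 in the splits that exchanged PBS replicate 2 for rHuEPO replicate 2 or 3. For interferon it was 4.273e-13, against 1.076e-11 in the split that exchanged PBS replicate 1 for rHuEPO replicate 3. Splits that put both slide 1 arrays together with PBS replicate 1 or PBS replicate 2 listed 2270 and 2844 genes at an unadjusted p under 0.05, against 736 for the real split, while the 2 that put them with rHuEPO replicate 2 or 3 listed 749 and 728. The real split keeps the slide 1 arrays on opposite sides. The other splits that did so listed 238, 125, 222, 362 and 202 genes, each fewer than the real one.

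Of 1010 genes that differed at least 2-fold between the untreated array and the PBS arrays, 908 (89.9%) differed in the same direction between rHuEPO replicate 1 and replicates 2 and 3.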
